A study of Homo sapiens with 16 samples.

How the data were processed

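The series holds 16 samples of HCT116 cells, of which 6 are poly(A) RNA-seq libraries and 10 are chromatin immunoprecipitation or input samples. Only the RNA-seq tables were analysed; the chromatin samples were not analysed here. Each RNA-seq library had a deposited table of FPKM values per gene symbol. Per the submitters' processing notes, reads were checked with FastQC, trimmed with cutadapt and aligned to hg19, with TopHat2 and Bowtie among the tools named; SICER is also named there. Versions of these tools, the program that made the FPKM values and the gene annotation are not given in the sources used here. No normalization beyond FPKM is named in the sources used here.

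The libraries were grouped from the labels into 3 transfections (NC, siEZH1, siUXT) by 2 treatments (PBS, TNF), with 1 library per condition. What the letters NC stand for is not given in the sources used here. All 6 tables list the same 28502 symbols, and 19326 are above 0 in at least 1 library. Symbols with identical values in all 6 libraries were merged, which left 17642 loci above 0. A locus was tested if its mean was at least 1 FPKM, which kept 11845 loci; 1035 of these carry several symbols and 408 several protein-coding ones, and their values cannot be assigned to 1 gene. Of the listed symbols, 22888 matched a current or older symbol in a RefSeq gene table, which was used only for gene type, names and gene spans. Without the counting program and strand setting, overlapping, antisense and near-identical genes are uncertain. Small nucleolar and other small RNAs are shorter than most sequenced fragments, and their FPKM values often switched between 0 and a high value.

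Values were analysed as log2(FPKM + 1). On this scale the change of genes with low FPKM is understated. The number of reads behind a value is not given. Where low values (under 0.4 FPKM) are whole multiples of 1 fragment, the ratio of those steps between libraries gives relative depth; with a tolerance of 2%, between 279 and 314 low loci per library lay at the most frequent ratio to NC PBS. The 10 largest loci held 12.4% to 14.5% of the FPKM sum over loci, and median-of-ratios size factors lay between 1.00 and 1.05, so the values were used as deposited. An exact 0 was read only as listed at 0, since it can be a failed estimate.

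The main test was limma (version 3.58.1 in R 4.3.3; lmFit and eBayes with trend) with an additive model of transfection and treatment over all 6 libraries, which leaves 2 residual degrees of freedom per locus, and with Benjamini-Hochberg adjustment over the loci tested and a threshold of 0.05. Its prior degrees of freedom were 4.42. The TNF response was estimated over the 3 transfections and each knockdown over both treatments, so the model takes any difference of the TNF response between transfections as error. For a knockdown, this error is the difference of its effect between treatments. The sample labels do not say whether the PBS and TNF libraries of a label came from separate transfections. If they did not, the error leaves out the spread between repeated transfections. Single pairs of libraries and differences of the TNF response have no residual degrees of freedom; for these the log2 ratios, the number of loci at least 2-fold apart and list medians are given without a test. A list's median was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Overlaps of the knockdowns are given with the value for independent lists and with a simulation of unchanged groups sharing 1 control. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

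The tests, the gene lists, the rule for named genes and most other settings below were fixed before the data were examined. The rule named, among loci with a mean of at least 1 FPKM, the 15 largest rises and 8 largest falls under TNF, the 10 largest rises and 10 largest falls for each knockdown, each among called loci with the same sign in every pair, filled where fewer were called by loci at least 1.5-fold apart the same way in every pair. It also named the 5 lowest and 3 highest differences of the TNF response against NC, up to 4 members per list, and 10 genes always given (EZH1, EZH2, UXT, SUZ12, EED, RELA, NFKB1, NFKBIA, TNFAIP3 and IL8). Only 5 loci met the rule for TNF falls at all. Because the rule named many small RNAs, it was applied again to protein-coding loci, a choice made after the data were seen. A gene that the rule selected for siUXT is not reported here.

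The 25 lists were NF-kB target genes, TNF receptor to NF-kB signalling components, PRC2 components, PRC1 components and H3K27 demethylases, the UXT-containing prefoldin-like and R2TP complex, interferon-stimulated genes, p53 target genes, mitotic genes, DNA replication genes, sterol biosynthesis genes, unfolded protein response and ATF4 target genes, glycolysis and hypoxia genes, Wnt target genes, developmental regulators often marked by H3K27me3, immediate early genes, apoptosis regulators, heat shock proteins and chaperonin CCT, lysosome and autophagy genes, epithelial to mesenchymal genes, cytoplasmic ribosomal protein genes, replication-dependent histone genes, mitochondrially encoded genes, nuclear genes of the mitochondrial respiratory chain, colonic epithelial markers, and markers of leukocytes, fibroblasts, endothelium and liver. None of the 13 mitochondrially encoded symbols is in the tables, so that list was not used. Genes shared by 2 lists, such as BBC3, PMAIP1, TNFRSF10B, ATF3, BTG2 and MYC, count in both.

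Other settings fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios and quantile scaling, eBayes without trend, a threshold of 0.1, fits without the block, leaving out each transfection pair, fold thresholds of 1.5 and 3, loci chosen by a single pair, and list means. Protein-coding loci only and leaving out each library were added after the data were seen. Fits that leave out a library or a pair keep 1 residual degree of freedom.

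The scripts were tested on simulated data with the real loci's means and spread, in 5 draws with 100 changed loci per fold size among 11845. All simulated libraries had the same spread at a locus and none stood apart, unlike the real ones, so the rates need not hold for these. For TNF they recovered 41.4% of 2-fold and 95.6% of 4-fold changes with 5.52% false calls; for siEZH1 they recovered 10% of 2-fold and 87.8% of 4-fold changes with 4.12% false calls. For the list percentiles, 40 simulated lists of 50 loci fell outside the central 95% in 2.5% of cases with no shift, 35% with a log2 shift of 0.1 and 97.5% with a shift of 0.3. The simulated loci varied independently of each other. These percents therefore do not cover lists whose members vary together, which can reach extreme percentiles more often.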

Results

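RNA was measured in HCT116 cells, an established human colorectal carcinoma line, after transfection with 1 of 3 small interfering RNA (siRNA) preparations and treatment with tumour necrosis factor (TNF) or with phosphate-buffered saline (PBS). The preparations were a control labelled NC, one against EZH1 (siEZH1) and one against UXT (siUXT). EZH1 encodes a histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2 (PRC2), and UXT encodes a small prefoldin-like protein. The 3 transfections and 2 treatments made 6 conditions with 1 library each, so no condition had a replicate. The series also held 10 chromatin samples, which were not analysed here. Expression as FPKM, fragment counts scaled by transcript length and library size, was listed for 28502 gene symbols. After symbols with identical values in all 6 libraries were merged into 1 locus, 11845 loci had a mean of at least 1 FPKM, and 11018 of these were protein coding. The FPKM of a library summed to between 617998 (NC PBS) and 649481 (siUXT TNF). The read depth itself was not given. Steps among low values put the depth of the NC TNF and siEZH1 TNF libraries at 0.718 and 0.719 of that of NC PBS, and the other libraries at 0.950 to 1.02.

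The siRNA against UXT lowered UXT in both siUXT libraries. UXT was at 62.2 FPKM in NC PBS and 59.6 in NC TNF, against 27.7 in siUXT PBS and 24.6 in siUXT TNF, which is 0.445 and 0.412 of the matched control. EZH1 differed less: it was at 5.45 and 5.12 FPKM in NC PBS and NC TNF and at 4.05 and 4.14 FPKM in the siEZH1 libraries, or 0.742 and 0.809 of the control. In the siUXT libraries EZH1 was at 6.27 and 6.24 FPKM. In limma's additive model with Benjamini-Hochberg adjustment over all loci, the UXT difference was -1.19 on the log2(FPKM + 1) scale with an adjusted p of 0.69, and the EZH1 difference was -0.30 with an adjusted p of 0.64. UXT passed the threshold when siEZH1 libraries were left out (limma, Benjamini-Hochberg adjusted p = 0.047 without the siEZH1 pair), and also adjusted over the list alone among the 14 tested loci of its prefoldin-like and R2TP complex (limma, Benjamini-Hochberg adjusted p = 0.0065). SUZ12, a core subunit that EZH1 and EZH2 both need in PRC2, was at 25.9 FPKM in siEZH1 PBS against 16.4 in NC PBS, and EED, another, at 1.49 times its NC PBS value. In the siUXT PBS library SUZ12 was at 3.92 FPKM and EED at 4.73, but in siUXT TNF at 14.7 and 12.3. EZH2, the paralog of EZH1, lay between 21.1 and 31.5 FPKM in the 6 libraries. RELA, the p65 subunit of NF-kB, lay between 30.7 and 46.9 FPKM.

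**Figure D1:**
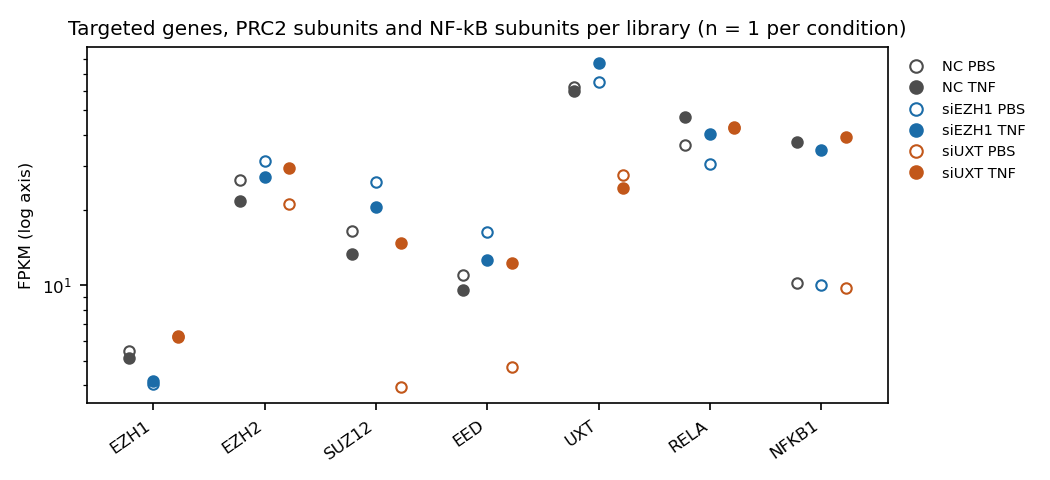
FPKM (log axis) of the targeted genes, other PRC2 subunits and NF-kB subunits in each of the 6 libraries, with open points for PBS, filled points for TNF and 1 colour per transfection. UXT lay at 27.7 and 24.6 FPKM in the siUXT libraries against 59.6 to 77.1 in the other 4, and SUZ12 was lowest in siUXT PBS at 3.92 FPKM.

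TNF, the cytokine that activates NF-kB through its receptor, raised chemokines, NF-kB inhibitors and BIRC3 in all 3 transfections. IL8, a neutrophil chemokine now named CXCL8, went from 0.307 to 149 FPKM in NC, from 0.447 to 96.5 in siEZH1 and from 0.321 to 132 in siUXT, a mean log2 change of 6.52 with an SD of 0.40 over the 3 transfections. CXCL1, of the same chemokine family, rose by 5.65 ± 0.25 (SD, n = 3 transfections) and BIRC3, an inhibitor of apoptosis, by 4.85 ± 0.38. The negative feedback genes TNFAIP3 (A20) and NFKBIA (IkB-alpha) rose by 4.07 ± 0.12 and 3.54 ± 0.20. Only ID2, an inhibitor of basic helix-loop-helix factors, fell past the threshold, from 105 to 36.2 FPKM in NC, with a mean log2 change of -1.22 ± 0.27, and no fall was called with a pseudocount of 0.1, no filter, size factors or eBayes without trend.

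Limma called 48 loci up and 1 down at a Benjamini-Hochberg adjusted p under 0.05, all 49 protein coding and with the same sign in the 3 pairs. The adjusted p in this limma test (Benjamini-Hochberg) was 1.2e-04 for IL8 and 0.043 for ID2. At an unadjusted p under 0.05 the count was 469, against 592 by chance. Among the 15 largest rises were further secreted or surface proteins. CXCL3 rose by 3.70 ± 0.46, ICAM1, a leukocyte adhesion molecule, by 3.73 ± 0.58, PLAU, the urokinase protease, by 3.11 ± 0.13 and SDC4, a heparan sulfate proteoglycan, by 2.95 ± 0.28. The chemokine gene CCL20 was listed at 0 in NC PBS and siUXT PBS and at 31.6, 19.8 and 13.8 FPKM under TNF in NC, siEZH1 and siUXT. CXCL2 was listed at 0 in siUXT PBS and at 26.4, 19.1 and 17.1 FPKM under TNF. RELB, an NF-kB subunit, rose by 3.36 ± 0.43, TNFAIP2 by 3.63 ± 0.50, IRF1, an interferon regulatory factor, by 2.87 ± 0.58 and NUAK2, an AMPK-related kinase, by 2.82 ± 0.71. Of the loci that filled the list of falls without being called, GATA2, a transcription factor gene, had a mean log2 change of -1.10 and MSX2, a homeobox gene, of -0.65. IFI27 and the small nucleolar RNA SNORA10 were lower in all 3 pairs, and both were listed at 0 in siEZH1 TNF. With the siUXT PBS library left out, a check added after the data were seen, limma called 293 loci up and 35 down, and 48 of the 293 were the 48 called with all libraries.

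**Figure D2:**
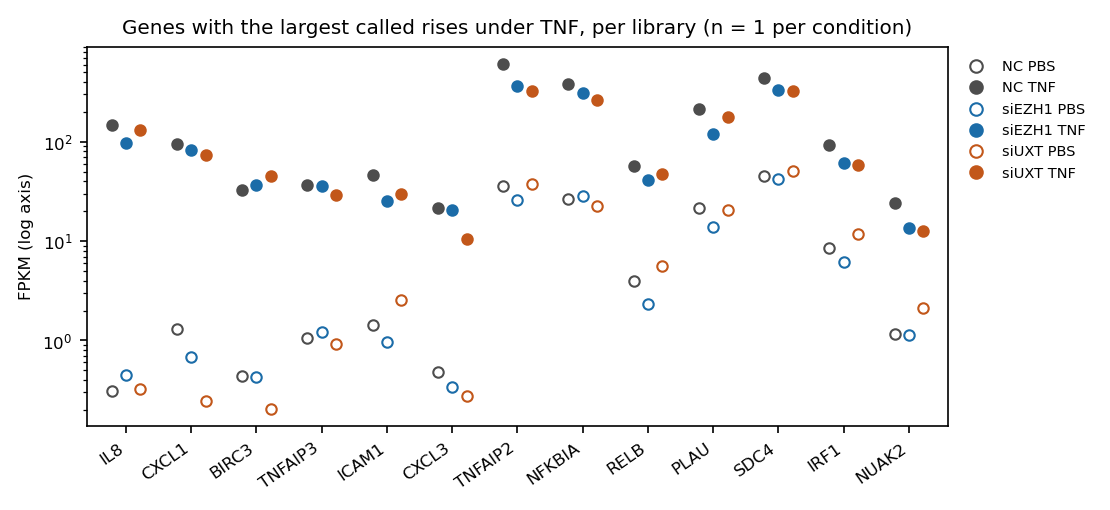
FPKM (log axis) per library of 13 of the 15 genes with the largest called rises under TNF, with open points for PBS and filled points for TNF; CCL20 and CXCL2 are left out because they were listed at 0 in at least 1 library. Each gene was higher under TNF in all 3 transfections, and NFKBIA went from between 22.8 and 28.2 FPKM to between 261 and 379.

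The response was concentrated in the list of NF-kB target genes. Of its 52 tested loci, 51 had a mean change above 0, 44 were higher under TNF in all 3 pairs, and 28 were called; 44 passed limma's test with Benjamini-Hochberg adjustment adjusted over the list alone. The list's median log2 change was 1.88 in NC, 1.74 in siEZH1 and 1.64 in siUXT, each above all 10000 random lists of matched expression (percentile 100), as a description of these libraries. Within it the NF-kB subunit genes NFKB1 and NFKB2 rose by 1.79 and 2.19, and the cytokine genes CSF1, CSF2 and IL32 by 2.44, 1.76 and 2.13. The signalling components that carry the signal from the TNF receptor to NF-kB, such as RELA and TRAF2, had 0 of 27 loci called and medians of -0.09, 0.01 and 0.07 in NC, siEZH1 and siUXT. A further 20 loci rose that were not on the NF-kB list. These included IRAK2, a kinase of interleukin-1 receptor signalling, PDGFB, a growth factor gene, at 2.52, JUNB and JUN, subunits of AP-1, at 2.24 and 1.83, IFNGR2, an interferon-gamma receptor chain, at 1.86, and OPTN, an autophagy receptor, at 1.30.

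Immediate early genes, which growth factors and stress induce within minutes, were the other list with several called members. JUNB, ATF3, JUN and DUSP5 were the 4 of 22 called, and limma's test with Benjamini-Hochberg adjustment adjusted over the list alone called 9 up and 1 down (KLF2, at -0.58). Its median was 0.45 in NC, 0.44 in siEZH1 and 0.46 in siUXT, at or above percentile 99.8. No locus was called over all genes among 33 interferon-stimulated, 32 p53 target or 25 apoptosis genes; adjusted over the list alone (limma, Benjamini-Hochberg), 5 interferon-stimulated genes rose and 1 fell. Those that rose included IFIH1 and DDX58, cytosolic RNA sensors, at 1.35 and 1.04. In the same way 8 p53 targets rose, among them the pro-apoptotic BBC3 (PUMA) at 0.99 and the death receptor gene TNFRSF10B at 0.82, both also among the 4 apoptosis regulators that rose with BIK at 1.04. The model had 2 residual degrees of freedom, and in simulated libraries it recovered 41.4% of 2-fold TNF changes and 95.6% of 4-fold ones. In that simulation no library stood apart, unlike siUXT PBS in the real data, so these rates need not hold here. The counts over all loci may miss many changes near 2-fold.

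After siEZH1, no protein-coding locus passed the test over all 6 libraries, but a set of genes differed in the same direction under both treatments. CLDN3 and CLDN4, tight junction proteins, were lower in both siEZH1 libraries: CLDN3 at 3.59 against 10.8 FPKM under PBS and 4.28 against 11.9 under TNF, and CLDN4 with log2 changes of -0.87 and -0.94. GDF15, a stress-induced cytokine of the TGF-beta family, was at 0.440 of its NC value under PBS and 0.391 under TNF, and UQCR10, a subunit of respiratory complex III, at 111 against 253 and 120 against 316. STC1, a secreted glycoprotein hormone, was higher at 3.22 against 1.02 FPKM under PBS and 3.32 against 1.02 under TNF.

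Limma called 0 loci up and 2 down for siEZH1 at a Benjamini-Hochberg adjusted p under 0.05, and 972 loci had an unadjusted p under 0.05. The 2 were the small nucleolar RNAs SNORA31 and SNORD15A, which were listed at 0 in all 4 knockdown libraries. At least 1.5-fold the same way under both treatments were 55 loci higher and 282 lower, against 9.34 and 36.9 for independent lists. Independence is only a reference here, since the PBS and TNF libraries of a label may share differences of a common transfection. Besides genes given here, the rule for named genes over all loci gave SNORA27, ZNF32-AS1 and LOC100129148 as higher and SNORA52, SNORA76, SNORA84, SNORA10 and RMRP, an RNA component of a ribonuclease, as lower. It gave, among protein-coding loci, a choice made after seeing the data, TPM4, a tropomyosin, with log2 changes of 0.82 and 0.96 under PBS and TNF, KIF20B, a mitotic kinesin, with 0.79 and 1.12, and RGS2, a regulator of G protein signalling, with 0.81 and 0.94. DDIT4L, ZNF530, SIMC1, YAE1D1, DNM3 and HSDL2 were the other higher ones. Among the lower ones SCAND1 had changes of -1.24 and -1.04, ZDHHC12, a palmitoyltransferase, -1.01 and -1.30, and the RTEL1 locus, which also holds TNFRSF6B in these values, -1.19 and -1.11. LRFN1, NPB and SUSD2 were also lower, and LHB was listed at 0 in both siEZH1 libraries. All 20 had limma Benjamini-Hochberg adjusted p values of at least 0.60. When the siUXT PBS library was left out, in a fit added after the data were seen, limma with Benjamini-Hochberg adjustment called all 20 and 1396 loci up and 1736 down in total; leaving out siUXT TNF gave 1339 and 1750. The spread of those fits came from the NC and siEZH1 pairs alone, with 1 residual degree of freedom. The 20 were chosen from these same pairs for large changes that agreed under both treatments, so their calls add no support. EZH1 itself, at a log2 change of -0.30, was not called in either fit. These calls therefore do not tie the changes to lower EZH1.

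Median values of mitotic and protein folding genes were higher in the siEZH1 libraries than in NC. In the fit over all 6 libraries, no member of these lists or of PRC2 was called for siEZH1. This held over all loci and adjusted over the list alone (limma, Benjamini-Hochberg). It depended on the libraries used: without siUXT PBS, members of each list were called, more of them up than down. Many loci outside these lists were called in that fit as well, so called members are no trait of these lists. As said above, its calls do not tie the changes to lower EZH1. Mitotic genes had a median log2 change of 0.23 under PBS and 0.29 under TNF, with 27 and 28 of 34 higher, among them TOP2A, a DNA topoisomerase, at 0.38 and 0.56 and the kinetochore gene MAD2L1 at 0.32 and 0.63. BIRC5 (survivin) went the other way at -0.62 and -0.46. Heat shock proteins and the chaperonin CCT had medians of 0.25 and 0.33, and HSP90AA1 was at 0.49 and 0.57. PRC2 components had medians of 0.25 and 0.31, with SUZ12 at 0.63 and 0.58. These medians lay at or above percentile 98.9 of random lists. Epithelial to mesenchymal genes, of which 18 of 26 were tested, had medians of -0.24 and -0.34 (percentiles 0.88 and 0.09). This list mixes epithelial and mesenchymal markers, so its median gives no direction between them. Adjusted over the list alone, limma's test with Benjamini-Hochberg adjustment called CLDN3 and CLDN4, both epithelial markers, down. The same adjustment called GDF15 down among p53 targets and BAD, a pro-apoptotic BCL2 family member, among apoptosis regulators. Of 84 developmental regulators that often carry trimethylated lysine 27 of histone H3, such as HOXC9 and TBX3, only 34 were tested. In the fit over all 6 libraries 0 of 34 were called, and their medians were -0.04 and 0.06 (percentiles 24.9 and 62.1). Members with a mean under 1 FPKM were not examined, so nothing is known here of the silent ones. PRC1 components and lysine 27 demethylases, such as RNF2 at 0.59 and 0.45, had medians of -0.10 and -0.05. Mitotic, PRC2 and chaperone lists had medians of the opposite sign in siUXT PBS, described next. The siEZH1 changes were also related to genomic gene span (Spearman correlation across loci 0.261 under PBS and 0.275 under TNF), so a length trend in these libraries was not excluded.

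After siUXT, the genes that differed from NC were mostly not the same in the PBS and TNF libraries. Under PBS, 710 protein-coding loci were at least 2-fold lower than in NC and 21 higher, but under TNF only 16 were lower and 31 higher. CDK1, the kinase that drives entry into mitosis, was at 19.7 FPKM in siUXT PBS against 80.4 in NC PBS, but at 69.8 in siUXT TNF against 64.6 in NC TNF. PFDN4 and VBP1, prefoldin subunits, were at 1.46 and 15.5 FPKM against 8.30 and 44.7 under PBS, and at 9.09 and 46.2 against 7.19 and 33.9 under TNF. Genes lower under both treatments included UXT itself, SIVA1, an apoptosis-associated gene (log2 changes of -0.76 under PBS and -1.24 under TNF), and PTP4A3, a protein tyrosine phosphatase (-0.79 and -1.84).

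Limma called 3 loci up and 2 down for siUXT at a Benjamini-Hochberg adjusted p under 0.05, with 432 loci at an unadjusted p under 0.05. All 5 were small nucleolar RNAs listed at 0 in several libraries: SNORA31 and SNORD15A were at 0 in both siUXT libraries, and SNORD15B, SNORA79 and SNORA62 were at 0 in all libraries except these. At least 1.5-fold the same way under both treatments were 41 loci higher and 33 lower, against 15.2 and 59.7 for independent lists. The rule for named genes also gave SCARNA16, SNORA67 and LOC100129148 as higher and SNORA57, SNORA76, SNORA84, LOC100133957, FKSG51 and ANXA2P2, a pseudogene, as lower. Among protein-coding loci, a choice made after seeing the data, the higher ones included PSORS1C1, FAM212A, STX3, a syntaxin of membrane fusion, with log2 changes of 1.06 and 0.90, HABP4 at 0.91 and 0.89 and TFB1M, a mitochondrial ribosomal RNA methyltransferase, at 1.01 and 0.78. ATP6V1E2, BHLHA15, SULF2 and STYXL1 were also higher. FAM72A, GTF2IRD2, ZNF92, LAGE3, HIST3H2A and SEPP1 were lower, and so was RPSAP58, which shares reads with the ribosomal gene RPSA and is uncertain. With the siUXT PBS library left out, the siUXT estimate came from the siUXT TNF library alone. In that fit UXT, PTP4A3, SIVA1, LAGE3, STX3 and HABP4 had log2 changes of -1.32, -1.94, -1.25, -1.05, 0.85 and 0.96. The 20 named protein-coding genes were chosen from these same libraries for changes that agreed under both treatments, so these values add no support. In fits that leave out either siUXT library, the lone siUXT library was assumed to vary like the other groups.

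**Figure D3:**
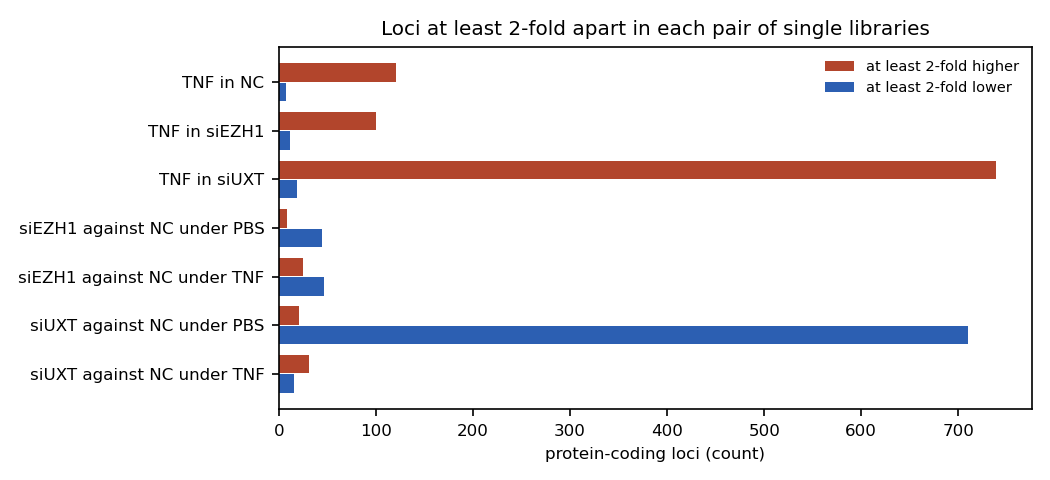
Number of protein-coding loci at least 2-fold higher or lower on the log2(FPKM + 1) scale in each of 7 pairs of single libraries. The pairs that use the siUXT PBS library stand out, with 710 lower in siUXT PBS than in NC PBS and 739 higher in siUXT TNF than in siUXT PBS.

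Group medians also differed between the siUXT PBS and siUXT TNF libraries, each set against its NC library. Mitotic genes had a median of -0.30 under PBS (percentile 0.03) and 0.11 under TNF, chaperones -0.18 and 0.30, and PRC2 components -0.36 and 0.24. Glycolysis and hypoxia genes had medians of 0.31 and -0.02, Wnt target genes 0.30 and 0.09, and epithelial to mesenchymal genes 0.30 and -0.14. Histone genes whose RNAs normally lack a poly(A) tail, a sign of RNA selection, had a median of 0.32 under PBS over 7 loci and -0.05 under TNF. The siUXT PBS library also stood apart from the other 5 by correlation: its highest Pearson r across loci with another library was 0.954, and each other library reached at least 0.976. The first principal component, with 50.6% of the variance, placed siUXT PBS at 49.3 and the other libraries between -27.8 and 8.94.

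**Figure D4:**
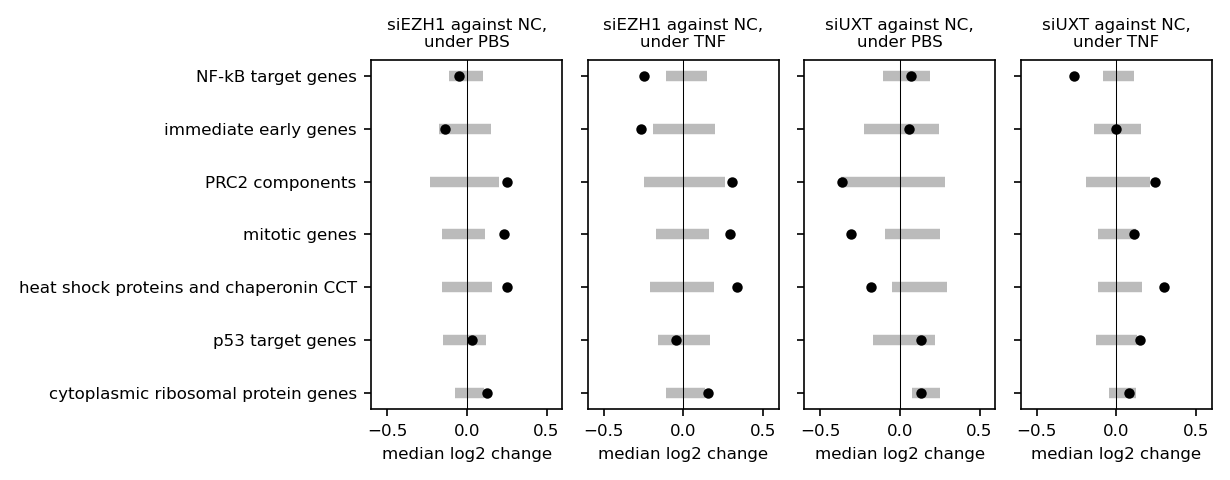
Median log2 change (points) of 7 fixed gene lists in the 4 knockdown pairs, with grey bars for the central 95% of 10000 random lists of the same size and expression. NF-kB target genes lay below the bars under TNF after both knockdowns (-0.25 and -0.26), and mitotic genes lay above them after siEZH1 and below them in siUXT PBS.

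The design also asks whether the knockdowns alter the TNF response, and NF-kB target genes reached lower levels under TNF after either of them. Under TNF, 43 of the 52 NF-kB targets were lower in siEZH1 than in NC (median log2 change -0.25) and 35 were lower in siUXT (median -0.26). Under PBS the medians were -0.05 and 0.07. TNFAIP2 reached 605 FPKM in NC, 366 in siEZH1 and 324 in siUXT, and ICAM1 46.5, 25.5 and 30.1. CD83, an activation marker, reached 54.4, 61.1 and 58.1, and BIRC3 32.6, 36.7 and 45.5, so not all targets followed.

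The response itself, TNF minus PBS, was smaller than in NC by a median of -0.13 on the log2 scale after siEZH1 (36 of 52 targets lower, percentile 0.01 among random lists) and of -0.35 after siUXT (40 of 52, percentile 0.09). For the 111 loci with a mean TNF log2 change of at least 1, the median differences were -0.12 (65 lower, 45 higher) and -0.35 (74 lower, 33 higher), both at percentile 0. The random lists were matched on expression and not on the TNF response, so they hold mostly loci that respond little. A small difference in response size between single libraries can thus give such percentiles, which say little about the knockdowns. Each siUXT response also subtracts the siUXT PBS library, which stood apart from the others. The NF-kB list's median against NC under TNF was similar after siEZH1 (-0.25) and siUXT (-0.26). Under PBS it was -0.05 and 0.07. For this list the larger siUXT response difference is thus no sign of a larger siUXT effect under TNF. The central range of its random lists was also wider for siUXT, -0.26 to 0.19, than for siEZH1, -0.04 to 0.09. By the naming rule the lowest and highest loci were noncoding loci, nearly all small RNAs listed at 0 in some libraries: after siEZH1 SNORD12B, MIR3911, SNORA3, SNORA20 and SNORA80B lowest and SNORA24, SNORA71C and 5S_rRNA highest, and after siUXT RNU6ATAC, SNORD12B, MIR3911, BC034020 and SNORA3 lowest and SNORA24, SNORA27 and Y16709 highest. Among protein-coding loci, S100A3, a calcium-binding protein, reached 21.4 FPKM under TNF in NC against 7.65 in siEZH1 and 9.55 in siUXT. RAET1L, CXCL2, STX11 and CCL20 were the others lowest after siEZH1, and ZZEF1, TRIML2 and CD83 were highest there. After siUXT, NUAK2, BCL3, an atypical IkB protein, CHAC1 and ICAM1 were lowest with S100A3, and KRTAP2-3, BIRC2, an inhibitor of apoptosis, and IFNGR1 were highest. BIRC2 and IFNGR1 had lower PBS values in siUXT, 4.38 against 11.8 and 8.45 against 19.1 FPKM. No test was possible, because each response is the difference of 2 single libraries, and both differences from NC share the NC pair. With loci chosen by the siEZH1 pair alone, the siEZH1 difference turned to 0.087.

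Set against each other directly, the siUXT and siEZH1 libraries differed in division genes and p53 targets under TNF, and NF-kB targets lay among the random lists. DNA replication genes had a median siUXT against siEZH1 change of -0.20 under TNF (37 of 39 lower), 32 of 34 mitotic genes were lower, and 27 of 32 p53 targets were higher (median 0.24). These compare single libraries without a test. Against NC under TNF, the mitotic medians were 0.29 after siEZH1 and 0.11 after siUXT, and the replication medians 0.16 and -0.06. The gap in division genes thus lay mostly in siEZH1 above NC and not in siUXT below it. NF-kB target genes had a median siUXT against siEZH1 change of -0.01 under TNF (percentile 36.0) and 0.16 under PBS (percentile 66.3), and their TNF response differed by -0.16 (percentile 24.6). Limma called 3 loci up in siUXT and 0 down at a Benjamini-Hochberg adjusted p under 0.05, with 1805 at an unadjusted p under 0.05; the 3 were SNORD15B, SNORA79 and SNORA62. With siUXT PBS left out the counts were 16 and 7, and with siUXT TNF left out 3564 and 3219. HABP4, an RNA-binding protein gene, was higher than in NC after both, at 14.5 and 14.6 FPKM in siUXT and 14.8 and 12.4 in siEZH1 against 7.26 and 7.43 in NC. SIVA1 and PTP4A3 were lower than in NC in all 4 knockdown libraries. Under TNF, 143 loci were at least 1.5-fold higher and 189 at least 1.5-fold lower than NC after both knockdowns, against 13.7 and 22.0 for independent lists. Under PBS the shared counts were 37 and 49 against 10.4 and 100. Across loci, which are not independent replicates, the changes correlated with Pearson r of 0.68 under TNF (covariance 0.117) and -0.12 under PBS (covariance -0.025). Over protein-coding loci that TNF did not induce, r was 0.69 under TNF and -0.32 under PBS. Unchanged groups that share 1 control gave a simulated r of 0.50 and covariance of 0.0990. Between pairs with no shared library, r was 0.39 for siEZH1 under PBS with siUXT under TNF and -0.32 for siEZH1 under TNF with siUXT under PBS. Part of the overlap under TNF may come from the shared control library.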

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

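The values here are results whose sign differed between transfections or treatments in single pairs of libraries. None of these differences was tested, because each pair is made of 2 single libraries. Loci listed at 0 in any library were left out, because a listed 0 can be a failed estimate.

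Mitotic and folding genes had TNF medians of opposite sign in siUXT and in the other transfections. Mitotic genes had a median log2 change under TNF of -0.179 in NC and -0.109 in siEZH1 but 0.266 in siUXT, and MAD2L1, a spindle checkpoint gene among them, had -0.605 in NC and 1.025 in siUXT. Heat shock proteins and the chaperonin CCT had -0.155 in NC, -0.056 in siEZH1 and 0.239 in siUXT, and after siUXT against NC they had -0.182 under PBS and 0.296 under TNF. PRC2 components had -0.192 in NC and 0.459 in siUXT. YAE1D1 was at -1.118 in siUXT against NC under PBS and 0.832 under TNF, and NDUFB3, a subunit of respiratory complex I, at -0.680 and 0.638. All of these involve the siUXT PBS library, which stood apart from the other 5.

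Other genes differed between the NC and siEZH1 pairs. LCN2, an iron-sequestering protein on the NF-kB list, had a TNF change of 0.669 in NC and -0.919 in siEZH1. HIST1H2AM, a replication-dependent histone gene, had 1.335 in NC and -0.990 in siEZH1, and after siEZH1 against NC it had 1.124 under PBS and -1.201 under TNF. ANXA2P2, a processed pseudogene of ANXA2, had -1.587 in NC and 1.102 in siEZH1, and RPSAP58 had -0.706 and 1.806; reads of both can be shared with their parent genes.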

How the results depend on the processing

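Of the 17 TNF genes named and called, 14 kept their call under every setting that used all 6 libraries; ID2, IRF1 and NUAK2 lost it in some, and none changed direction. With no filter, 23 of the 48 loci called up by TNF were called, and no others. Leaving out libraries one at a time or in pairs, and testing protein-coding loci only, were in part chosen after seeing the data. Fits that leave out a library or pair have 1 residual degree of freedom, and those leaving out NC or siEZH1 libraries took the same spread for all loci of equal expression. The TNF test compared TNF with PBS within each transfection, and without blocks TNF falls were 2. Except where said below, the cause was not tested. Read depth is unknown, so no precision from counts can be given for low genes.

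For the 48 called up and 1 down by TNF, the 1 down became 0 with a pseudocount of 0.1, no filter, size factors or eBayes without trend, and 2 at a threshold of 0.1; fits leaving out libraries gave 100 to 294 up and 24 to 35 down. The siEZH1 calls, 0 up and 2 down, became 1 down at a mean of at least 5 FPKM and 0 down for protein-coding loci, since the called small RNAs then leave the test, and 14 to 1396 up and 24 to 1750 down with libraries left out. The siUXT calls, 3 up and 2 down, became 0 and 0 with a pseudocount of 0.1 and for protein-coding loci, 0 and 1 at a mean of at least 5 FPKM, and 21 to 1425 up and 25 to 2179 down with libraries left out. For siUXT against siEZH1, the 3 up became 0 with a pseudocount of 0.1, at a mean of at least 5 FPKM, with size factors and for protein-coding loci, and 16 to 3564 up and 7 to 3219 down with libraries left out. The log2 change of UXT, -1.19, lay between -1.32 and -1.06 with libraries left out and then passed the threshold in 5 of these fits.

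Counts of loci at least 2-fold apart moved with the threshold and pseudocount by construction. For TNF in NC, siEZH1 and siUXT, 177, 158 and 834 became 320, 287 and 1318 with a pseudocount of 0.1, 637, 542 and 2421 at 1.5-fold, and 82, 81 and 220 at 3-fold; at a mean of at least 5 FPKM the NC and siEZH1 counts were 112 and 97. For siEZH1 under PBS and TNF, 95 and 137 became 266 and 322 with a pseudocount of 0.1, 164 and 214 with 0.5, 50 and 67 at a mean of at least 5 FPKM, 52 and 71 for protein-coding loci, 862 and 1156 at 1.5-fold, and 32 and 38 at 3-fold. For siUXT under PBS, 817 became 1288 with a pseudocount of 0.1, 2434 at 1.5-fold and 178 at 3-fold. For siUXT under TNF, 98 became 245 with a pseudocount of 0.1, 154 with 0.5, 43 at a mean of at least 5 FPKM, 47 for protein-coding loci, 732 at 1.5-fold and 34 at 3-fold.

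The NF-kB list's TNF medians in NC, siEZH1 and siUXT were 2.18, 2.09 and 1.93 with a pseudocount of 0.1, 2.04, 1.96 and 1.85 with 0.5, 0.94, 0.82 and 0.77 with no filter, which adds low genes, and 2.13, 1.93 and 1.84 as means. Its response difference from NC was -0.21 as a mean for siEZH1 and -0.20 with no filter for siUXT. For TNF-induced loci the siEZH1 difference of -0.12 was -0.0901 with a pseudocount of 0.1, -0.0933 with 0.5, -0.0927 at a mean of at least 5 FPKM, -0.15 with size factors, -0.20 as a mean, and -0.30 with loci chosen by the NC pair, and it reversed to 0.087 with loci chosen by the siEZH1 pair. The siUXT difference of -0.35 was -0.23 with a pseudocount of 0.1, -0.46 with quantile scaling and -0.61 with loci chosen by the NC pair, and it reversed to 1.44 with loci chosen by the siUXT pair. Choosing loci by a pair raises that pair's response by selection alone.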

Other observations

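The tests chosen only after their result was seen were those of relative depth, of shuffled ratios, of the siUXT knockdown acting alike under both treatments, of TNF-induced loci chosen by the siEZH1 pair for the siUXT response, and of a shared high NC TNF library.

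Several fixed gene groups were described only in part above or not at all. Wnt target genes had a median TNF log2 change of -0.14 in NC, -0.10 in siEZH1 and -0.27 in siUXT, and no locus of 15 was called. AXIN2, a feedback inhibitor of Wnt signalling, went from 22.6 to 15.6 FPKM in NC, from 34.3 to 24.3 in siEZH1 and from 28.1 to 19.5 in siUXT, while MYC on the same list went from 83.2 to 120, from 70.6 to 98.0 and from 107 to 136. Of the unfolded protein response and ATF4 targets, ATF3 was called under TNF and 3 of 32 passed adjusted over the list alone in limma's test with Benjamini-Hochberg adjustment, with CHAC1, a glutathione-degrading enzyme, at 1.10 and PPP1R15A (GADD34) at 0.92. The list's medians after siEZH1 were -0.14 and -0.07 and after siUXT 0.19 and 0.05 under PBS and TNF. Of lysosome and autophagy genes OPTN was called under TNF, and SQSTM1 (p62) passed adjusted over the list alone at 0.80 (limma, Benjamini-Hochberg); the list's medians after siUXT were 0.21 and 0.10. Among developmental regulators, limma with Benjamini-Hochberg adjustment adjusted over the list alone called GATA2 and MSX2 down and DLX2 and WNT10A up under TNF. KDM6B, a lysine 27 demethylase, was at 7.47 against 4.70 FPKM under TNF in NC, and was not called.

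DNA replication genes had TNF medians of -0.08 in NC, -0.05 in siEZH1 and -0.21 in siUXT, with medians of 0.16 under both treatments after siEZH1, with CCNE2 (cyclin E2) at 0.56 and 0.70, and 0.02 and -0.06 after siUXT. Cytoplasmic ribosomal protein genes had medians of 0.12 and 0.15 after siEZH1, with members on both sides: RPL11 was at 0.53 and 0.44, but RPLP1 at -0.82 and -0.74 and RPLP2 at -0.79 and -0.65. After siUXT their medians were 0.13 and 0.08. Nuclear respiratory chain genes had medians of 0.02 and 0.05 after siEZH1 and 0.15 and 0.13 after siUXT. Sterol biosynthesis genes had medians of 0.11 and 0.03 after siEZH1 and 0.17 and -0.01 after siUXT. The prefoldin-like and R2TP complex of UXT had medians of 0.12 and 0.07 after siEZH1 and 0.13 and 0.13 after siUXT; URI1, a partner of UXT, was at 6.83 FPKM in siUXT PBS and 14.1 in siUXT TNF against 13.2 and 10.4 in NC. Of 17 colonic epithelial markers only 4 were tested, with CDX2 between 6.46 and 9.95 FPKM. Of 19 markers of other cell types only COL1A1 and SERPINA1 were tested, at up to 8.26 and 4.83 FPKM.

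The siUXT PBS library differed from NC PBS by 772 loci at least 2-fold lower, with CDK1 and SUZ12 among them. Low depth is argued against by the library's relative depth of 0.950, above the 0.718 of NC TNF, but not by the 85.2% of the lower loci at 5 FPKM or more in NC PBS (71.2% of all loci), since shuffled ratios gave 89.1%. After median-of-ratios scaling, which corrects for a few dominant genes, 834 were lower; quantile scaling, which forces equal distributions, left 554, and an effect of the UXT knockdown alike under both treatments is argued against by their median of 0.14 in siUXT TNF against NC TNF. A bias by gene length stays open: genomic span, known for 96.4% of these loci, had a Spearman correlation of -0.21 with the change across all loci with a span, near the size seen in pairs without this library (-0.209 for TNF in NC, 0.275 for siEZH1 under TNF), and the transcripts' own length and GC content were not analysed here. An effect of the knockdown present only without TNF, or a difference in the handling of this 1 library, may each account for it and cannot be told apart with 1 library.

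The siEZH1 changes raise a related hypothesis. In the fit without the siUXT PBS library 3132 loci were called for siEZH1, and 87.1% of them had the same sign in siUXT TNF minus siUXT PBS, against 72.5% expected from all loci. That 72.5% is not a value for unrelated changes. Over all loci the siEZH1 changes already had a Spearman correlation of 0.51 with siUXT TNF minus siUXT PBS, under PBS and under TNF. The 772 loci had a median of 0.26 in siEZH1 PBS and 0.35 in siEZH1 TNF against NC, and 90.5% were higher in siEZH1 TNF. The siEZH1 changes may thus lie partly on the axis that sets the siUXT PBS library apart, with the opposite sign, but the share lay between the values foreseen for that axis being and not being the cause. Across protein-coding loci that TNF did not induce, the siEZH1 changes under PBS and TNF correlated at 0.70, and at 0.60 after removing the part shared with siUXT TNF minus siUXT PBS, so an siEZH1 effect apart from this axis stays open as well.

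The lower TNF response after the knockdowns depends on how loci are chosen. With the 122 loci chosen by the siEZH1 pair the siEZH1 difference was 0.087, so choosing loci can turn its sign, and with the 795 chosen by the siUXT pair the siUXT difference was 1.44, which says little because 749 of those loci were lower in siUXT PBS than in NC PBS. The siUXT difference was -0.37 with loci chosen by the siEZH1 pair, which enters neither response, below the random lists' 2.5% bound of -0.16. This does not exclude selection, nor a part from the siUXT PBS library, which the siUXT response subtracts. Across protein-coding loci that TNF did not induce, the response in siEZH1 correlated at 0.50 with that in NC and at -0.25 with that in siUXT. Loci chosen as high in the siEZH1 pair may by this alone be higher in NC than in siUXT, unlike the random lists. For the fixed NF-kB list, a high NC TNF library shared by both comparisons may lower both knockdowns alike, and siUXT TNF against siEZH1 TNF gave a median of -0.0114 (percentile 36.0), as it would also if both knockdowns lowered these genes equally. A weaker response after both knockdowns and a high control library cannot be told apart with 1 NC TNF library.

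For the 49 loci called for TNF, the 6 libraries can be divided into groups of 3 in 10 ways, too few for a share under 0.05, and 3 of the 10, the real one included, called as many. The real grouping called 49 and the highest other 464. The groupings with 464 kept the NC and siEZH1 pairs together and parted only the siUXT pair, which points to a structure of the samples, the distance between the siUXT PBS and siUXT TNF libraries. Among groupings that parted all 3 pairs, the real one called 49 and the others 1, 0 and 0.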
